A study of Homo sapiens with 6 samples.

How the data were processed

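The series profiled RNA from U937 cells, a human myeloid line that the labels describe as lacking p53, after infection with an empty vector, wild-type p53, p53-V272M or p53-R273H. The vector and wild-type cells served as negative and positive controls. Cells of each mutant were sequenced untreated and after 24 h with 10 µM potassium antimony tartrate (PAT), a trivalent antimony compound. Total RNA was made into libraries with a TruSeq RNA kit, per the labels' protocols. There were 6 libraries, 1 per group, and no library was left out. Whether reads were counted by strand was not given in the sources used here, so overlapping and antisense genes may share reads.

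FastQC, cutadapt, STAR and HTSeq are named, without versions, per the submitters' processing notes, with the genome build hg38. The deposited table held 19872 genes and named no unit. Its deposited values behaved as FPKM, that is, reads scaled to gene length and to the library total. The worth of 1 read, found from the commonest low values, gave library totals of 24173198 reads for vector, 19715499 for wild type, 21880364 for V272M, 26620805 for V272M with PAT, 30159007 for R273H and 23455635 for R273H with PAT. Reads per gene were recovered by finding a gene length that gave whole reads in every library of a set, to within 1e-05 reads plus rounding of the file. The annotated length was that of the longest transcript in the control set and of all exons merged in the mutant set. It gave whole reads for 9.05% of genes in the control set and 43.7% in the mutant set. For the others whole-number lengths were searched and the one nearest the annotated length was taken, and ratios within a set do not depend on this length. Reads that are multiples of the true number would have common divisors too often. Of genes with a searched length and over 50 reads in each library, 51.8% had a common divisor in the control set, where random whole numbers would give 39.2%. In the mutant set 7.78% did, where 7.61% would be given. Reads of some control-set genes were therefore probably too high and their intervals too narrow. This check was chosen after the data were seen.

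The values fell into 2 sets that the authors had processed differently. The 4 mutant columns had a value for every gene, and their recovered reads made up 97.9% to 98.4% of the library totals. The vector and wild-type columns had no value for 1445 genes, among them all 13 mitochondrially encoded genes, and their recovered reads came to 124% of the totals. The excess was not resolved. Of 11609 genes with reads in both sets, 63.2% had gene lengths over 1.2-fold apart between the sets, and the median ratio of mutant-set to control-set length was 1.31. Both values depend in part on the different annotated lengths chosen for the sets, since searched lengths were taken nearest to them. They do not measure the lengths used by the authors alone. Ratios between a mutant library and the vector or wild-type library therefore mix biology with processing. Their counts and percentiles describe the libraries and were not tested. Symbols that a spreadsheet had turned into dates (14) were restored from the gene identifiers, and all 19872 identifiers were found in GENCODE release 29, which gave the coordinates. A pair of identifiers shared a symbol, and the 1 with the lower mutant-set values was left out.

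The choices below were made before the data were examined, except where stated. Because the file held a normalized unit where counts had been assumed, the log2 ratios written for that case were used. FPKM values were scaled within each set by the trimmed mean of M-values on recovered reads (30% trimmed by ratio, 5% by level), 0.1 was added, and log2 ratios were taken. They understate the ratio of low genes. Ratios between the sets were centred on the trimmed mean over genes. Scaling within each set and this centring were chosen after the values were seen to fall into sets processed apart. A gene was measured in a comparison with an FPKM of at least 1 in at least 1 library of a set compared, and was counted as higher or lower with an absolute log2 ratio of at least 1. The pseudocount of 0.1 and the FPKM minimum of 1 were set once the unit was known. Folds printed for single genes within a comparison are ratios of recovered reads scaled to the library, with no pseudocount and with an exact (Clopper-Pearson) 95% interval. The difference between lines used reads plus 0.5 and a normal approximation for its interval. Recovered reads, and with them the intervals and the ranking of genes by interval, were added once the unit was known. Intervals cover counting error only, since the reads carry no molecular identifiers. Where the lower library had 0 reads, the lower bound of that interval is printed after the words at least.

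A single library per group leaves no replicate check, so no p-value across genes is given for these ratios. Each of 22 gene lists, fixed beforehand, was described by the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the 2.5th to 97.5th percentile is said to stand apart in those libraries. Percentiles describe the libraries and are no test of the treatment. The lists covered core p53 targets, p53 targets shared with other stress pathways, G2/M and G1/S genes, NRF2 targets, metallothioneins with SLC30A1, heat shock genes, the integrated stress response, chaperones of the endoplasmic reticulum, interferon and NF-κB genes, and monocyte and immature myeloid markers. They further covered cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, mitochondrially encoded genes, replication histones and markers of lymphoid, erythroid, epithelial and fibroblast cells. No member of the erythroid, epithelial or fibroblast lists reached the FPKM minimum (0 of 7, 0 of 5 and 0 of 5).

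The PAT effect common to both mutant lines was tested with limma on log2(FPKM + 0.1), with a mean-variance trend, the mutant line as a block and Benjamini-Hochberg adjustment at 0.05. The 2 lines act as replicates, so 4 libraries and 3 coefficients leave 1 residual degree of freedom. The residual of a gene is the spread between lines, but the variance used was drawn largely from other genes (prior degrees of freedom 19.0). An SE or p below is therefore no measure of how alike the lines were for that gene. The test asks about the mean over both lines. A quasi-likelihood count test had been planned and was replaced because the deposited unit was not counts.

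Named genes followed a fixed rule. It took 18 fixed genes, the 8 higher and 8 lower genes whose counting bound lay farthest from 0, and up to 4 members of each described list that met the size rule. For limma it took the 8 genes of lowest p in each direction. Not every gene it took is named below. Of the fixed genes left out, CDK1, MCM2 and ATF3 met the size rule neither in wild type over vector nor with PAT in either line. HSPA1A had a log2 ratio of -1.26 in wild type over vector, and TP53INP1 did not reach the FPKM minimum. A further gene of the rule is not reported here. Alternatives were other scalings, pseudocounts, filters and thresholds, the fit without the line block, and leaving out each library.

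On data simulated from the real means and library sizes (dispersion 0.01), the size rule counted 67 of 67 genes changed 3-fold, 66 of 66 changed 6-fold and 4 of 67 changed 1.5-fold for PAT in V272M, with 7 of 9498 unchanged genes. For wild type over vector it counted 67 of 67, 66 of 66 and 1 of 67, with 1 of 9812 unchanged genes. For limma, 46 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered, with 8 of 9571 unchanged genes called. Changed genes were drawn only from those above a minimum of expected reads, so recovery of lower genes was not tested. The limma simulation gave every gene the same length. The dispersion was assumed and not estimated from these libraries. In the limma simulation both lines had the same PAT fold, so it does not show how the test behaves where the lines respond differently. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.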

Results

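RNA-seq was performed on U937 cells, a human myeloid line labelled p53-null, that carried an empty vector, wild-type p53 or the p53 mutants V272M and R273H. The mutant cells were also profiled after 24 h with 10 µM potassium antimony tartrate (PAT). The question of the series was the rescue of mutant p53 by PAT. Each of the 6 groups had 1 library, so no difference below has a replicate check unless stated. Library totals ranged from 19715499 to 30159007 reads. The vector and wild-type libraries formed a set processed apart from the 4 mutant libraries, and levels were compared within a set except where stated.

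**Figure D1:**
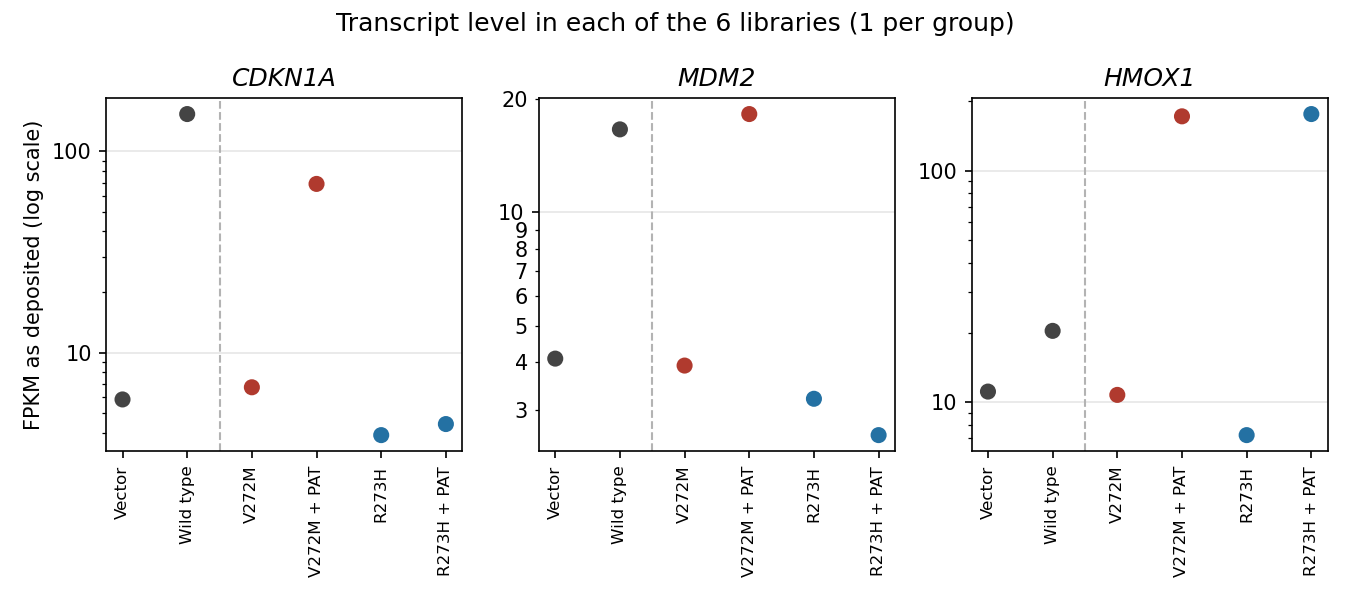
FPKM (log scale) of the p53 targets CDKN1A and MDM2 and of the haem oxygenase gene HMOX1 in each of the 6 libraries; each point is 1 library, and the dashed line separates the 2 sets processed apart. CDKN1A stood at 153 in wild type and 68.9 in V272M with PAT against 4.42 in R273H with PAT, while HMOX1 stood at 171 and 175 in the treated libraries.

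The first comparison set wild-type p53 against vector, the positive against the negative control. Classical p53 targets were higher with wild-type p53. CDKN1A, the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339, hg38), was 25.5-fold higher (95% counting interval 22.9 to 28.6), from an FPKM of 5.85 to 153. MDM2, the ubiquitin ligase that targets p53 (chromosome 12, 68808176 to 68850686), was 3.95-fold higher (3.73 to 4.19). The apoptosis gene BBC3 was 5.53-fold (4.84 to 6.33), the death receptor gene FAS 2.76-fold (2.18 to 3.51) and SESN1 3.26-fold (2.69 to 3.99) higher.

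Of 32 measured core p53 targets, 13 were higher by the size rule and 0 lower, with a median log2 ratio of 0.89, at the 100th percentile of matched random lists. BTG2 (8.02-fold, 6.39 to 10.2), TRIM22 (6.19-fold, 5.31 to 7.24) and FDXR (4.68-fold, 4.29 to 5.10) led the list after CDKN1A. BAX was 1.84-fold higher (1.77 to 1.92), short of the size rule. Among 8 measured p53 targets shared with other stress pathways, 4 were higher (median log2 1.17, 100th percentile), among them GADD45A (3.06-fold, 2.47 to 3.82) and DDIT4 (2.64-fold, 2.32 to 3.01). GDF15, a secreted stress cytokine, had 79 reads in wild type and 0 in vector and was at least 25-fold higher (lower 95% counting bound).

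Wild-type p53 went with differences beyond p53 targets. The monocyte and macrophage markers had a median log2 ratio of 0.76 (100th percentile), with 5 of 16 higher and 0 lower. NCF1, a subunit of the phagocyte oxidase, was 19.5-fold (17.2 to 22.3), the integrin genes ITGAX 6.59-fold (4.78 to 9.27) and ITGAM 3.46-fold (2.76 to 4.37), and S100A9 3.11-fold (2.62 to 3.71) higher. NCF1 has near-identical pseudogenes, so its reads are uncertain. Cholesterol synthesis genes were higher as a group (median 0.87, 100th percentile, 8 of 17 higher), led by MSMO1 (3.18-fold, 2.72 to 3.73), MVD (2.86-fold, 2.71 to 3.03) and INSIG1 (2.49-fold, 2.39 to 2.60). NF-κB genes had a median of 0.68 (100th percentile, 4 of 14 higher), with NFKB2 2.27-fold (2.17 to 2.39) and TNFAIP3 2.33-fold (2.13 to 2.55) higher. Interferon genes stood at 0.34 (98.4th percentile, 1 of 13 higher), the member being the chemokine gene CXCL10 (2.58-fold, 1.90 to 3.55).

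The protein-folding lists and, of the proliferation lists, G1/S alone had medians below the central 95% of random lists with wild-type p53. Heat shock genes had a median of -0.61 (0th percentile, 1 higher and 2 lower of 16) and endoplasmic reticulum chaperones -0.54 (0th percentile, 1 lower of 15). HSP90AA1 was 2.26-fold lower (2.22 to 2.31) and HSPA5, the chaperone BiP, 2.42-fold lower (2.37 to 2.48), whereas BAG3 was 2.24-fold higher (1.72 to 2.94). G1/S genes had a median of -0.27 (0.26th percentile, 0 of 26 lower by the size rule). The integrated stress response stood at -0.28 (0.64th percentile), though NUPR1 of that list was 41.9-fold higher (18.9 to 115, from 6 reads in vector). The metallothionein list stood at -0.54 (0.04th percentile). MYC was 1.65-fold lower (1.61 to 1.70). G2/M genes (-0.13), NRF2 targets (-0.11), immature myeloid markers (-0.13), hypoxia and glycolysis genes (-0.20), ribosomal proteins (0.04), replication histones (-0.09) and lymphoid markers (0.39) lay inside the central 95% of random lists. The histone gene HIST1H2BJ was 3.90-fold lower (1.59 to 11.5, on 28 and 6 reads).

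In all, 420 of 10111 genes were higher and 18 lower with wild-type p53 (419 and 17 when the counting interval also had to exclude equality, a choice added after the data were seen). Besides CDKN1A, the genes with the farthest counting bounds had few or no reads in vector. CYP4F2 (141 reads against 0, at least 45.1-fold) and CYP4F3 (44.5-fold, 23.9 to 93.5) encode fatty acid hydroxylases and are close paralogs whose reads may be shared. UNC13A (57.8-fold, 26.2 to 159) and the collagen gene COL5A1 (53.3-fold, 22.5 to 166) were others. The lower genes included HSPA6 (5.13-fold lower, 4.28 to 6.18), the MHC class II gene HLA-DRA (3.95-fold, 2.48 to 6.58) and ODC1 (2.27-fold, 2.20 to 2.34). Counts depended on low genes: with a pseudocount of 1 there were 210 higher and 8 lower. Recovered reads of some genes in this set were probably multiples of the true number, which leaves folds alone but makes intervals too narrow and alters bounds given as at least.

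The next comparison set V272M cells with PAT against untreated V272M cells. Several p53 targets that were higher with wild-type p53 were higher here too. CDKN1A was 10.1-fold higher with PAT (9.17 to 11.1), from an FPKM of 6.73 to 68.9. MDM2 was 4.57-fold (4.29 to 4.87), FAS 4.52-fold (3.92 to 5.22), SESN1 6.57-fold (5.58 to 7.77) and ZMAT3, an RNA-binding p53 target, 17.4-fold (14 to 21.9) higher. TRIM22 was 11.7-fold (10.6 to 13.0), BAX 2.57-fold (2.41 to 2.75) and BBC3 3.57-fold (2.94 to 4.34) higher.

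Of 30 measured core p53 targets, 20 were higher with PAT in V272M and 0 lower (median log2 1.33, 100th percentile). The p53 targets shared with other stress pathways had a median of 1.10 (100th percentile, 4 of 7 higher), among them GADD45A (4.52-fold, 3.55 to 5.82) and the death receptor gene TNFRSF10B (2.88-fold, 2.73 to 3.04). GDF15 had 0 reads without and 2 with PAT, too few for a ratio.

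Metal and oxidant response genes were also higher in V272M with PAT. HMOX1, which encodes haem oxygenase 1, was 15.7-fold (14.4 to 17.1), the ferritin heavy chain gene FTH1 5.09-fold (4.93 to 5.26), NQO1 2.13-fold (1.93 to 2.35) and the cystine transporter gene SLC7A11 2.66-fold (2.23 to 3.19) higher. These were the 4 of 15 NRF2 targets that met the size rule (median log2 0.33, 100th percentile). The metallothionein genes MT2A (3.65-fold, 3.54 to 3.77) and MT1F (2.74-fold, 2.45 to 3.06) were the 2 of 6 higher in their list (median 0.71, 100th percentile). Members of the metallothionein family share sequence, so reads may be split among them.

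Monocyte markers (median 0.68, 4 of 15 higher) and interferon genes (0.65, 1 of 10 higher) both lay at the 100th percentile with PAT in V272M. NCF1 was 3.97-fold (3.48 to 4.54), ITGAX 3.40-fold (2.74 to 4.26) and the interferon-induced gene OAS3 2.39-fold (2.13 to 2.68) higher. Ribosomal proteins had a small positive median (0.21, 100th percentile, 0 of 24 meeting the size rule). Heat shock (-0.52, 0th percentile), cholesterol synthesis (-0.42, 0.01th percentile) and G2/M genes (-0.32, 1.01st percentile) had lower medians. Of these lists only INSIG1 met the size rule, 2.41-fold lower (2.32 to 2.5). CCNB1, the mitotic cyclin B1, was 1.61-fold lower (1.54 to 1.68) and the replication helicase gene MCM7 2.02-fold lower (1.96 to 2.07). G1/S genes (-0.25), immature myeloid markers (-0.25), hypoxia and glycolysis (-0.24), the integrated stress response (-0.25), endoplasmic reticulum chaperones (-0.06), NF-κB genes (-0.05), mitochondrially encoded genes (0.05) and lymphoid markers (0.34) lay inside the central 95%. Of the replication histones 2 were measured in the mutant set, too few for a list median, and HIST1H2BJ was 7.51-fold higher (4.02 to 15.5, on 11 and 102 reads).

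In V272M, 278 of 9771 genes were higher and 59 lower with PAT. Several with the farthest bounds were nearly silent without PAT: COL5A1 (619 reads against 0, at least 135-fold), PXT1 (at least 66.1-fold), CYP4F2 (at least 37.3-fold), APOBEC3H (at least 27.2-fold) and CYP4F3 (32.6-fold, 17.6 to 68.6). SBF2 was 32.1-fold higher (28 to 37.1), from 203 to 8059 reads. TMEM158 (4.39-fold lower, 3.54 to 5.48), CTXN1 (3.16-fold, 2.71 to 3.68) and the chemokine gene CXCL2 (5.82-fold, 2.53 to 15.6, on 33 and 7 reads) were among the lower. With a pseudocount of 1, there were 125 higher and 15 lower.

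**Figure D2:**
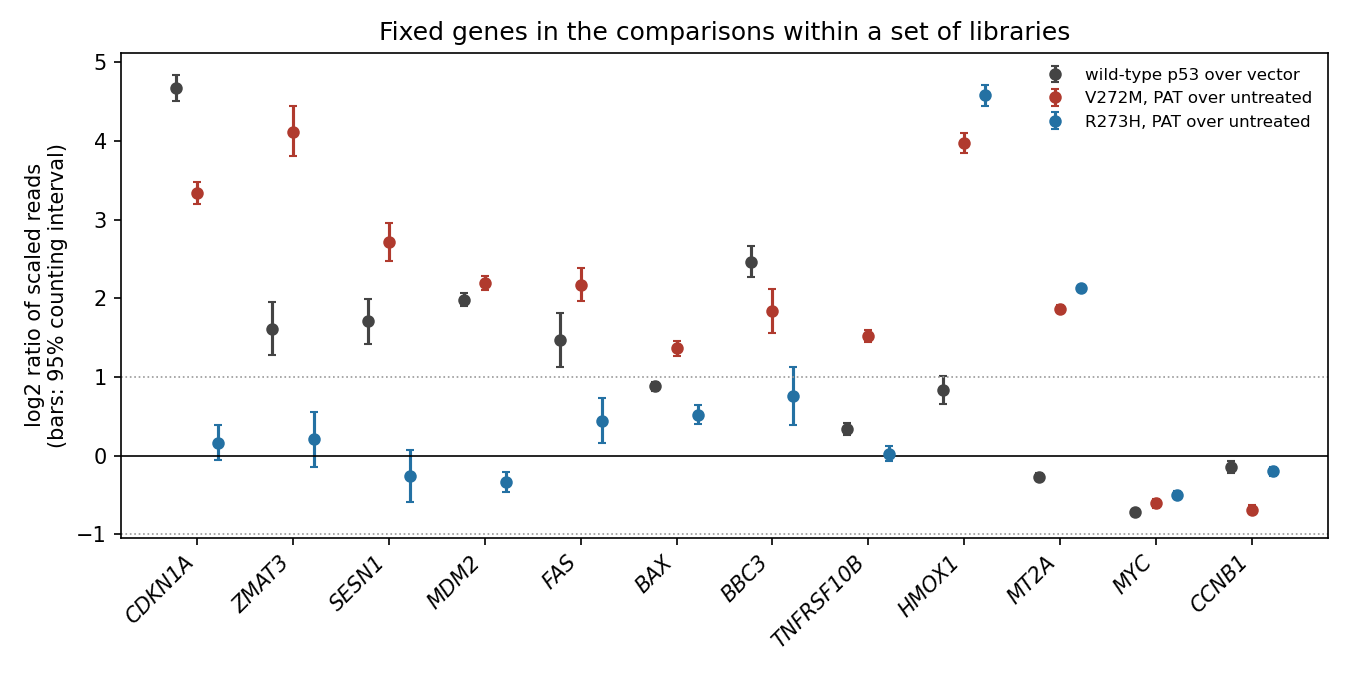
Log2 ratio of scaled reads for 12 of the fixed genes (x axis) in wild type over vector and in PAT over untreated for V272M and R273H; points are ratios of 1 library to another, bars the 95% counting interval, and dotted lines the size rule. CDKN1A, ZMAT3, SESN1 and MDM2 were above the line in wild type and V272M and within it in R273H, while HMOX1 and MT2A were above it in both mutants.

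PAT was then compared with no treatment in R273H cells, where metal and oxidant response genes were higher and none of the fixed p53 targets met the size rule. HMOX1 was 23.9-fold (21.9 to 26.2), FTH1 5.15-fold (4.97 to 5.33), MT2A 4.39-fold (4.27 to 4.5) and MT1F 3.48-fold (3.14 to 3.86) higher. CDKN1A was 1.12-fold the untreated level (0.959 to 1.31), SESN1 0.836-fold (0.665 to 1.05), ZMAT3 1.15-fold (0.905 to 1.47) and TNFRSF10B 1.02-fold (0.951 to 1.09), all with intervals that included equality. MDM2 was 0.790-fold the untreated level (0.723 to 0.863). BAX (1.44-fold, 1.32 to 1.56), BBC3 (1.69-fold, 1.31 to 2.19) and FAS (1.36-fold, 1.12 to 1.66) were higher by less than that rule.

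None of 30 core p53 targets met the size rule in R273H (0 higher, 0 lower), and their median log2 ratio of 0.06 lay at the 81.8th percentile. The stress-shared targets had a median of 0.21 (90th percentile, 0 of 7). NRF2 targets (0.54, 5 of 15 higher) and metallothioneins (0.90, 2 of 6 higher) lay at the 100th percentile, with OSGIN1 (2.82-fold, 2.36 to 3.37) and NQO1 (2.35-fold, 2.15 to 2.58) among the former. Monocyte markers (0.66, 3 of 15 higher) and interferon genes (0.38, 1 of 10 higher) stood at the 100th percentile as well. S100A8 was 8.11-fold (3.14 to 26.7), ALOX5AP 2.08-fold (1.93 to 2.26) and ITGAX 2.28-fold (1.87 to 2.79) higher.

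Cholesterol synthesis genes (-0.28, 0.01th percentile), G2/M genes (-0.22, 0.12th percentile) and immature myeloid markers (-0.23, 1.32nd percentile) had lower medians in R273H with PAT. INSIG1 was 2.12-fold lower (2.05 to 2.20) and PRTN3, which encodes the granule protease proteinase 3, 2.46-fold lower (2.41 to 2.52). PRTN3 was 2.01-fold lower (1.97 to 2.05) in V272M. Ribosomal proteins (0.09, 99.6th percentile), mitochondrially encoded genes (0.10, 97.9th percentile) and 3 lymphoid markers (0.63, 98.9th percentile) had higher medians, the last led by CD79A (3.07-fold, 2.36 to 4.02). Heat shock (-0.12), G1/S (-0.06), the integrated stress response (0.07), chaperones (-0.00), NF-κB (0.06) and hypoxia genes (-0.06) lay inside the central 95%. HIST1H2BJ was 2.13-fold higher (1.45 to 3.17). In R273H, 104 genes were higher and 28 lower of 9771, against 30 and 7 with a pseudocount of 1.

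**Figure D3:**
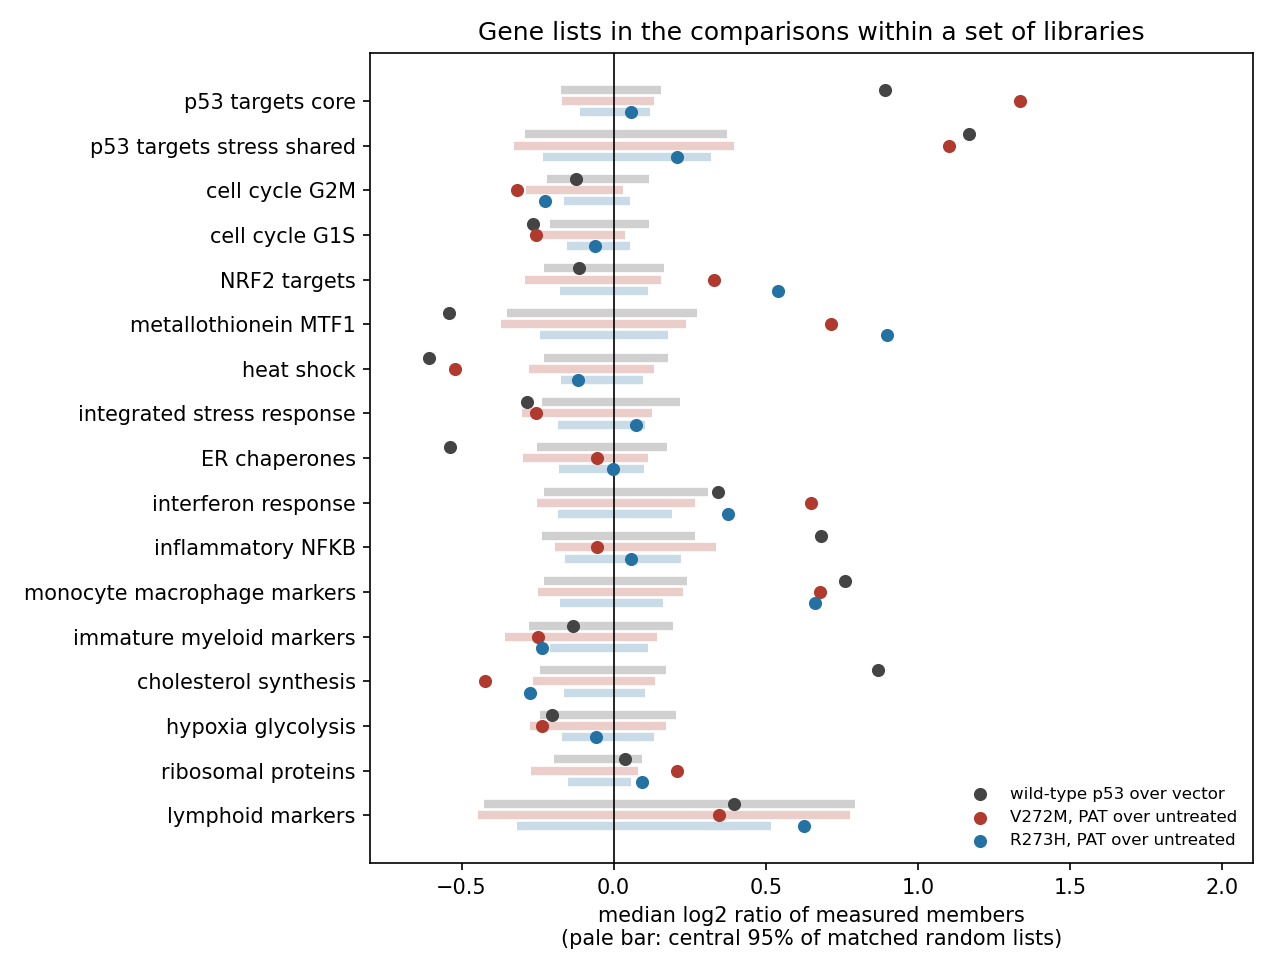
Median log2 ratio (x axis) of each gene list with a median in all 3 comparisons within a set; points are medians over measured members and pale bars the central 95% of 10000 matched random lists. The core p53 targets stand at 0.89 in wild type and 1.33 in V272M with PAT, and at 0.06, inside the bar, in R273H.

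The difference between the PAT responses of the 2 mutants was taken gene by gene. Core p53 targets were among the genes with the farthest bounds. The ratio with PAT in V272M over that in R273H was 9.01 for CDKN1A (7.53 to 10.8), 15.0 for ZMAT3 (10.9 to 20.6), 9.64 for TRIM22 (8.22 to 11.3), 7.82 for SESN1 (5.94 to 10.3) and 5.78 for MDM2 (5.19 to 6.44). Of 30 core targets, 18 had a difference of at least 1 in log2 toward V272M and 0 toward R273H (median 1.26, 100th percentile). For HMOX1 (0.655, 0.578 to 0.742) and MT2A (0.833, 0.80 to 0.867) the ratio of ratios was below 1, that is, toward R273H.

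Other groups differed between the mutants in smaller steps. Stress-shared p53 targets had a median difference of 0.87 (100th percentile, 3 of 7 toward V272M). Monocyte markers (0.18, 98.6th percentile) and ribosomal proteins (0.05, 99.4th percentile) leaned to V272M. Heat shock genes (-0.42, 0th percentile), the integrated stress response (-0.41, 0th percentile) and G1/S genes (-0.18, 1.94th percentile) leaned to R273H, with 0 members of any of these 3 lists at the size rule. Across all 9771 genes, 135 had a difference toward V272M and 49 toward R273H. SBF2 (30.2, 24.0 to 38.1) led the former, while PDE6G (6.2-fold toward R273H, 3.38 to 11.4) and C4orf48 (3.56-fold, 2.71 to 4.67) were among the latter. The difference has no residual between replicates and was not tested.

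**Figure D4:**
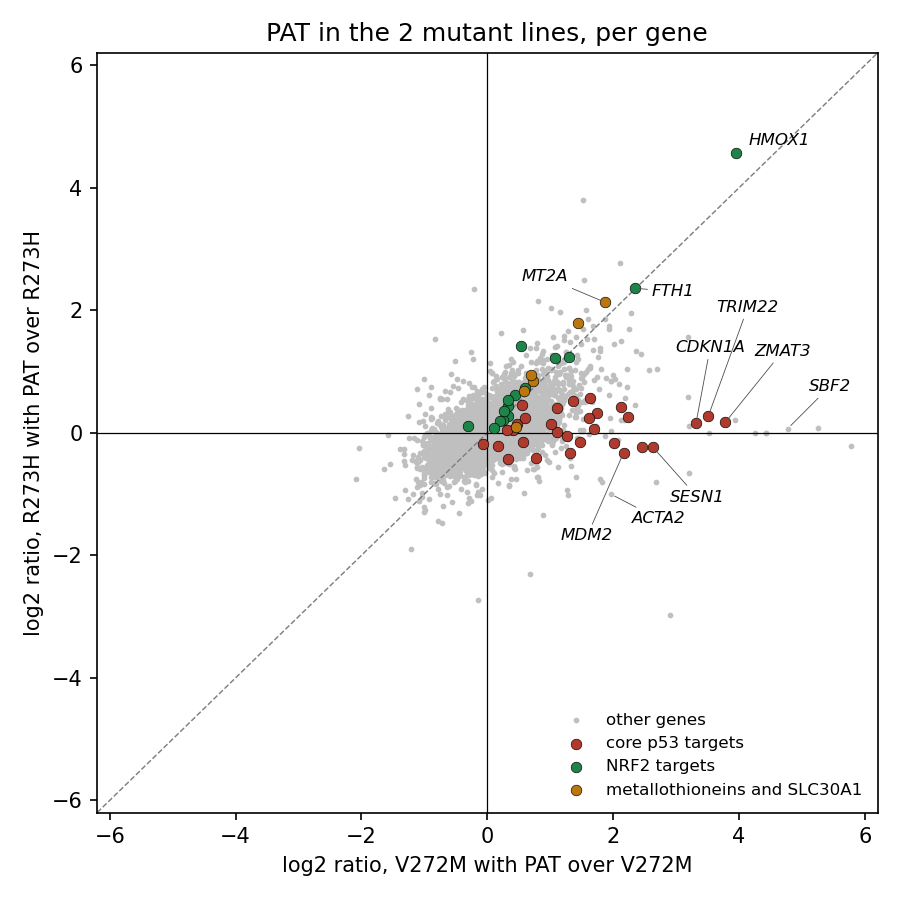
Log2 ratio with PAT in V272M (x axis) against that in R273H (y axis) for genes measured in the mutant set; each point is a gene, coloured for core p53 targets, NRF2 targets and metallothioneins with SLC30A1, and the dashed line marks equal ratios. HMOX1 (3.96 and 4.56) lies near the dashed line, and CDKN1A (3.32 and 0.16) lies near the x axis.

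Before treatment few genes differed between the 2 mutant lines by the size rule. Of 9771 genes, 29 were higher in V272M and 14 in R273H, and the SD of the log2 ratio across genes was 0.23, against 0.47 for PAT in V272M. CDKN1A was 1.72-fold higher in V272M (1.5 to 1.99) and BAX 1.52-fold (1.40 to 1.66). The core p53 targets had a median of 0.06 (97.6th percentile, 0 of 30 at the size rule) and monocyte markers 0.25 (100th percentile). Stress-shared p53 targets (0.29, 99.5th percentile), immature myeloid markers (0.15, 98.6th percentile) and heat shock genes (0.14, 99.1st percentile) also had higher medians in V272M. Mitochondrially encoded genes (-0.21, 0th percentile), metallothioneins (-0.21, 0.06th percentile) and G2/M genes (-0.06, 1.25th percentile) had lower medians. MYBPC3 was 4.31-fold higher in V272M (3.26 to 5.76), and the lipase gene LIPA 3.25-fold (2.28 to 4.76) and LANCL1 5.64-fold (3.53 to 9.49) lower.

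The PAT effect common to both lines was tested with limma, the lines serving as replicates of the treatment and most of the variance coming from other genes. HMOX1 rose by a mean log2 of 4.26 (SE 0.13, limma adjusted p = 9.8e-15), FTH1 by 2.35 (SE 0.11, limma adjusted p = 6.6e-12) and MT2A by 1.9998 (SE 0.11, limma adjusted p = 1.6e-10), each higher in 2 of 2 lines. HIST1H2BK (1.73), MT1F (1.62), the hexokinase gene HK3 (1.59), UBA7 (1.73) and TNFRSF14 (2.12) followed. PRTN3 fell by 1.15 (SE 0.11, limma adjusted p = 7.9e-07) and INSIG1 fell by 1.17 (SE 0.11, limma adjusted p = 1.1e-06). The fatty acid synthase gene FASN (-1.0025), SELENOT (-1.13) and MCM7 (-0.93) also fell. MYC fell by 0.55 (SE 0.11, limma adjusted p = 0.0028).

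By list, 9 of 15 NRF2 targets rose (11 adjusted over the list alone) and 0 fell. Of 6 metallothionein list members, 5 rose (6 adjusted over the list alone). Among monocyte markers, 10 of 15 rose and LYZ, the lysozyme gene, fell (11 and 1 adjusted over the list alone), with ALOX5AP at 1.01. Among interferon genes, 5 of 10 rose (7 adjusted over the list alone), including IFI6 (0.79) and IRF7 (0.64). Cholesterol synthesis genes fell in 9 of 17 cases (11 adjusted over the list alone), among them SQLE (-0.49), and G2/M genes in 7 of 22 (9 adjusted over the list alone), among them PLK1 (-0.67) and CDC20 (-0.64). Of heat shock genes 6 of 16 fell and 1 rose (11 and 1 adjusted over the list alone). The list members named here were chosen after their values were seen.

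Among the other lists, 5 of 7 stress-shared p53 targets rose (5 adjusted over the list alone). Their median log2 ratio was 1.10 in V272M but 0.21 in R273H, where 0 of 7 met the size rule. Of immature myeloid markers 4 of 11 fell, PRTN3 and MYC among them, and 1 rose, with the same counts adjusted over the list alone. Of G1/S genes 4 of 26 fell and 1 rose, likewise unaltered. Chaperones of the endoplasmic reticulum fell in 3 of 15 cases (4 adjusted over the list alone) and integrated stress response genes in 3 of 14, with 0 risen (4 and 2 adjusted over the list alone). NF-κB genes rose in 2 of 13 cases, ribosomal proteins in 2 of 24 and lymphoid markers in 1 of 3, and hypoxia and glycolysis genes fell in 2 of 14 cases and rose in 1, all with the same counts adjusted over the list alone. Mitochondrially encoded genes rose in 2 of 13 cases (3 adjusted over the list alone). Both measured replication histones rose, HIST1H2BJ by 1.87 and HIST1H1C by 0.60.

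In total 707 of 9771 genes rose and 780 fell at an adjusted p of 0.05. The test is of the mean over the lines, with its variance drawn largely from other genes (prior degrees of freedom 19.0 beside 1 residual), so it also called genes that differed in V272M alone. It called 19 of 30 core p53 targets as higher (21 adjusted over the list alone), CDKN1A among them with log2 ratios of 3.32 in V272M and 0.16 in R273H (limma adjusted p = 0.0042). MDM2, at 2.16 and -0.33, was not called (limma adjusted p = 0.051). Of the genes called, 238 higher and 65 lower were at least 1.5-fold in both lines. Without the line block 414 rose and 392 fell. That fit with 1 library left out, in which the lone library of a line is assumed to vary like the others, called 182 and 46 without V272M, 19 and 11 without V272M with PAT, 174 and 140 without R273H, and 534 and 598 without R273H with PAT.

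The genes that were higher with wild-type p53 were followed into the PAT comparisons, which share no library with it. Of 304 such genes measured in both sets, 85.5% were above 0 with PAT in V272M (median log2 0.68), against 48.9% of all 9250 genes. The lists of higher genes had 99 in common, where independent lists would share 7.82. In R273H, 75.7% were above 0 (median 0.33), with 34 in common against 3.02. Untreated V272M over R273H gave a median of 0.09 and 11 in common against 0.72. Some went the other way: 3 were lower with PAT in V272M against 1.74 if independent, 3 with PAT in R273H against 0.72, and 4 in V272M over R273H against 0.39. Across genes, the log2 ratio of wild type over vector had Pearson's r = 0.45 and Spearman's rho = 0.34 with PAT in V272M, and r = 0.38 and rho = 0.40 with PAT in R273H. The PAT responses of both lines had r = 0.55 and rho = 0.58. Genes are not independent replicates, and no p-value is given for these 3 correlations.

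Of the 99 genes higher both with wild-type p53 and with PAT in V272M, 22 were also higher in R273H and 16 were on the p53 lists. CYP4F2, COL5A1, CYP4F3, CDKN1A, SBF2 and TRIM22 were among the 99 and none of these was among the 22; CYP4F2 and COL5A1 had 0 reads in both R273H libraries. The 12 measured genes lower with wild-type p53 had medians of -0.35 in V272M and -0.21 in R273H.

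Comparisons of mutant with control-set libraries cross the boundary of processing, and set and group cannot be told apart in them. CDKN1A was at 0.84 in V272M and 0.07 in R273H relative to vector, and MDM2 at 0.58 and 0.30. Core p53 targets had a median of 0.23 in V272M (89.1st percentile, 4 higher and 5 lower of 32) and 0.13 in R273H (71.4th percentile, 5 higher and 8 lower), both inside the central 95%. G2/M genes were at 0.96 and 0.89 (100th percentile) and ribosomal proteins at -1.503 and -1.43 (0th percentile). In all, 778 genes were higher and 2027 lower in V272M, and 938 and 2106 in R273H, of 10226. Without centring, scaled to total library size only, the median of all genes shifted by -0.64 in both, the counts were 83 and 3910, and 96 and 3958, and the core p53 medians turned to -0.41 and -0.52.

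V272M with PAT was set beside wild type in the same way, and p53 targets are described here. CDKN1A was lower in treated V272M than in wild type (log2 -0.48), BBC3 was at -1.63 and BAX at -1.06. ZMAT3 (2.64), FAS (1.58), SESN1 (1.33), TNFRSF10B (1.11) and MDM2 (0.81) were higher. The core list had a median of 0.49 (99.7th percentile, 9 higher and 6 lower of 32). Its direction hung on the scaling: scaled to total library size only it was -0.18.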

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

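The genes below had PAT effects of opposite direction in the mutant lines, with counting intervals that excluded equality on both sides. The difference was not tested, since each value rests on 1 library per group. MDM2 was chosen beforehand, the other genes after their values were seen, while the test of the pattern described last was chosen before the result was seen.

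MDM2 had a log2 ratio of 2.16 with PAT in V272M (1155 to 6520 reads) and -0.33 in R273H (1300 to 810 reads). ACTA2, the smooth muscle actin gene, was at 1.96 (30 to 168 reads) and -1.003 (42 to 13 reads). Its FPKM was only 0.468 without and 0.186 with PAT in R273H. ACTA2 (chromosome 10, 88935074 to 88991339) overlaps FAS (88990582 to 89015785), so the genes may share reads. KLRF1, which encodes a lectin-like receptor, was at 1.28 (23 to 74 reads) and -1.01 (78 to 29 reads). The histone gene HIST1H2AJ was at 2.90 (1 to 16 reads) and -2.98 (8 to 0 reads); these last values depend on the pseudocount and histone genes share sequence.

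MDM2 stood for a wider pattern, the higher level of core p53 targets in V272M with PAT. A response to PAT that both lines share and that needs no p53 is argued against as the whole cause. The list's difference between lines was at the 100th percentile of random lists. A shared part stays open, because no vector cells with PAT were sequenced. The list had a median log2 ratio in V272M of 1.32 with median-of-ratios factors and 1.36 with total library size only, but another scaling shifts all genes almost alike and so is no test of the list. Also open is how the lines differ otherwise. Mutation, expression level and culture came together in each line, and with 1 library of each none was separated from the others. A restored activity of V272M itself is a hypothesis that may account for the pattern and was not tested against them.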

How the results depend on the processing

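In wild type over vector, both PAT comparisons and their difference, the direction of the p53 core list median held under all 7 alternatives. Untreated V272M over R273H was not varied. The median ranged from 0.76 to 0.93 in wild type over vector, from 1.11 to 1.36 with PAT in V272M, from 0.05 to 0.08 with PAT in R273H (62.4th to 83.3rd percentile) and from 0.87 to 1.35 for the difference. Alternatives with recovered reads plus 0.5, with intervals, and with other pseudocounts or robust variance in limma were chosen after seeing the data. The limma fit with the mutant line as block paired the treated and untreated library of each line. For comparisons of 1 library with another, no paired analysis was possible because each is a single pair. The planned count tests were not run, since the deposited unit was not counts. Of all alternative values, 643 stayed close to the value reported, 63 moved, 3 were stronger, 2 weaker and 10 reversed. Depth limits the lower genes most, and counts by size moved with the treatment of low genes, as follows; beyond fewer or more genes tested, the cause was not tested.

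With a pseudocount of 0.4, PAT in V272M gave 30 lower genes, PAT in R273H 61 higher and 15 lower, and the difference between lines 32 toward R273H. With a pseudocount of 1, higher and lower counts were 210 and 8 in wild type over vector, 125 and 15 in V272M, 30 and 7 in R273H, and 58 and 12 for the difference. With no filter they were 735 and 78, 569 and 180, 280 and 120, and 440 and 284. At an FPKM of at least 5 they were 194 and 11, 104 and 24, 31 and 9, and 43 and 10; higher counts over vector were 492 in V272M and 587 in R273H, and the core list in V272M over vector was at 0.30, outside the central 95%. With recovered reads plus 0.5, wild type had 28 lower genes, V272M over vector 505 higher, and the core list of treated V272M over wild type was at 0.22, inside the central 95%.

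Between sets, scaling to total library size only gave 83 higher and 3910 lower genes for V272M over vector and 96 and 3958 for R273H. Of medians outside the central 95%, it turned the G1/S (-0.14), heat shock (-0.12) and cholesterol (-0.16) medians in V272M over vector and the G1/S (-0.30) and heat shock (-0.23) medians in R273H over vector. In treated V272M over wild type it turned the core p53 (-0.18), G2/M (-0.048), G1/S (-0.38), NRF2 (-0.22) and heat shock (-0.019) medians. Medians inside the central 95% turned too, among them core p53 over vector in V272M (-0.41) and R273H (-0.52). The missing centring shifts every gene alike.

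In limma, no filter gave 449 higher and 368 lower genes, and no line block 414 and 392. Leaving out each library from the fit without the block gave 19 to 534 higher and 11 to 598 lower, with fewer samples. Other limma settings gave 658 to 719 higher and 706 to 810 lower.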

Other observations

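The genes and tests of this part were chosen after the results were seen, except the test of gene lengths over all genes. In all, 66 genes were higher with PAT in both mutants where independent lists would share 2.96, and 7 were lower where 0.17 would be shared. The scavenger receptor gene MARCO had log2 ratios of 1.93 in V272M and 1.74 in R273H. The chemokine gene CXCL16 was at 1.58 and 2.01, the adaptor gene TYROBP at 1.45 and 1.204, and the inflammasome gene MEFV at 1.49 and 1.45. The haem transporter gene SLC48A1 (1.22 and 1.51) and the interferon-induced genes IFI35 (1.68 and 1.74) and UBA7 (2.01 and 1.46) were also on both lists. MEFV was at 1.23 and MARCO at 0.88 in wild type over vector.

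Some genes on no fixed list were also higher with wild-type p53 and with PAT in V272M but near their untreated level in R273H. PIDD1, which encodes a p53-induced death domain protein, had log2 ratios of 1.198, 1.52 and 0.23 in these comparisons. PHLDB3 was at 1.66, 1.51 and 0.05. Of the 99 genes higher in both the former comparisons, 80 were on no list. An FPKM of at least 1 in an R273H library was reached by 73 of the 99, genes on the lists included. Of these, 27 were within 1.5-fold of their untreated level in R273H, among them CDKN1A, TRIM22 and MDM2 of the p53 lists. The count was not made for unlisted genes alone. Over all 99 genes the median log2 ratio with PAT in R273H was 0.60, so PIDD1 and PHLDB3 do not stand for the 99.

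Genes higher with wild-type p53 also stood higher with PAT in R273H, where the core p53 list did not stand apart. Targets of p53 on no list were not tested. Whether low-expressed genes that vary in every comparison are the cause was not settled. Among genes with an FPKM of at least 5 in at least 1 library of each set, 8 were shared against 0.514 for independent lists, or 15.6 times. The overlap thus did not need genes that were low in every library of a set. A gene could pass by the library where it was higher, so genes low in the other library were not removed and the filter cannot decide the question. A shared myeloid maturation may be involved, because monocyte markers were higher in each comparison, but immature markers in wild type stood only at the 26.3rd percentile of random lists, which leaves this undecided. Genes that vary at any level stay open as a cause. Untreated V272M over R273H, with no PAT in either library, also shared 11 higher genes with wild type against 0.72 for independent lists. Genes that went the opposite way with PAT in R273H were also more than independent lists would give (3 against 0.72). No replicate library showed how far such genes differ between untreated cultures.

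The mutant libraries differed from the control set far more than the control libraries from each other. With lengths taken out, the SD across genes of log2 V272M over vector was 2.35 times that of wild type over vector (1.25 against 0.53), but errors in searched lengths inflate the former and cancel in the latter. Among 287 genes whose annotated length gave whole reads in both sets, the SD was 1.68 times as large (bootstrap 95% interval over genes 1.27 to 2.11), which does not settle whether it lies above the bound of 1.5 set for lengths as the cause. Gene lengths, counting rules, sequencing batch and biology stay open, since set and group coincide.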
